A study of Mus musculus with 12 samples.

How the data were processed

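Expression was measured in the nucleus accumbens of C57BL/6J mice on Illumina MouseWG-6 v2.0 bead arrays, with 12 arrays in 4 treatment groups of 3. Each array carried RNA pooled from the punches of 4 mice, so the arrays are separate pools and the mice within a pool cannot be told apart. Groups and replicate numbers were taken from the sample labels.

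The authors subtracted background from the intensity values and quantile normalized them in BeadStudio and went on to GeneSpring, per the series text, and the version of that program is not given in the sources used here. Both deposited tables hold intensity on a linear scale that was already quantile normalized across the 12 arrays. In the table presented as raw, sorted values differed between arrays by at most 0.725 intensity units and no background had been taken off. The other deposited intensity table equalled it minus a constant of 60.7 on every array, with a largest deviation of 0.00586. The raw table also carries, per the file headers, a detection p-value for each probe and array. Because quantile normalization was already done, differences in total signal between arrays had been removed and could not be examined. The design had foreseen background correction with neqc, limma's method for non-normalized signals, should the table hold such signals. It did not, so the branch for normalized values applied.

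The background-subtracted values were floored at 10 and taken to log2. Of 45281 probes, 25478 were kept because their detection p was under 0.05 on at least 3 of the 12 arrays, and 19247 were detected on all arrays. Of the kept values, 6.34% lay at the floor. The table gave 1 gene symbol for 34885 probes, several for 18 and none listed for 10378. Entrez numbers of 34807 probes matched the reference gene table, and 0 symbols changed. Kept probes with 1 symbol covered 12732 genes, of which 5408 had more than 1 kept probe. A gene is represented by its brightest kept probe unless another probe is mentioned. No pair of arrays held identical values, and correlations between arrays ran from 0.973 to 0.992.

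Differences were fitted with limma 3.58.1 in R 4.3.3, with lmFit and eBayes on all 12 arrays and no covariate, giving 8 residual and 2.16 prior degrees of freedom. Tests were two-sided. P-values were adjusted over the 25478 kept probes of each comparison by the Benjamini-Hochberg method, with a threshold of 0.05. Counts under the rule in the series text, at least 1.3-fold with an unadjusted p under 0.05, are called the series criteria. The test behind the authors' own p is not given in the sources used here, so limma's p took its place. Fold changes against a group in which no array detected the probe are given as lower bounds, computed from the lowest detected value of each array. These bounds, written as at least, cover only the unknown level of the undetected group. They carry no sampling error and hold for the background-subtracted values alone, so other processing can give smaller folds. All 6 pairwise comparisons and a moderated F test over the 4 groups were made. Errors of log2 differences are standard errors from limma, and intervals cover 95%. The number of arrays limits the precision.

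A total of 27 gene lists were written down before the data were examined. They comprised immediate early transcription factors, activity-induced effectors, glucocorticoid-responsive genes, circadian clock genes, heat shock genes and chaperones, enzymes of H3K9 and other H3 lysine methylation, histone acetylation and DNA methylation enzymes, spine actin regulators, glutamate receptors, dopamine, opioid and cannabinoid signalling, ribosomal proteins and oxidative phosphorylation subunits. The others were markers of medium spiny neurons (shared, D1 and D2), interneurons, cortical neurons, neighbouring septal, hypothalamic and thalamic tissue, choroid plexus, ependyma, astrocytes, oligodendrocytes and their precursors, microglia, vessels, blood and meninges. Each was tested with limma's camera at a preset correlation of 0.01 between genes, adjusted over the 27 lists within a comparison. Camera with an estimated correlation, and fry, were run beside it. Single members were also adjusted over the list alone.

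The genes named follow a rule fixed before the data were examined. Ehmt2 and Ehmt1 are always given. In each comparison and direction the genes past the adjusted threshold are named, filled up to 6 by those with the smallest p among genes that met the series criteria. For each list described, the 4 members with the smallest p may be named. Immediate early and effector genes could be given in every comparison had they passed the adjusted threshold in 1, and none did. Genes outside the rule were chosen after their values were seen and are marked so.

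The replicate numbers are shared by the groups, so it was checked whether same-numbered arrays deviated together. Correlations of deviations from the group means exceeded 0.1 for every number in repeated against saline (0.47, 0.34 and 0.13), withdrawal against saline (0.39, 0.29 and 0.17) and repeated against acute (0.44, 0.25 and 0.26). In these the numbers pair the arrays by that criterion, although the labels name no shared batch, day or litter. In acute against saline, withdrawal against acute and withdrawal against repeated at least 1 correlation was lower, down to 0.03.

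The fits were tested on simulated data built from the spread and means of the 25478 probes. For repeated against saline, 3.1% of probes changed 1.3-fold passed the adjusted threshold, as did 18.7% of those changed 1.5-fold, 53% of those changed 2-fold and 74.3% of those changed 3-fold. The series criteria found 36.6%, 69.5%, 90.6% and 97.9%. In simulations of acute against saline with no changed probe, a mean of 854 probes (793 to 894) met the series criteria and 0.1 passed the adjusted threshold. All simulated noise was drawn independently for each probe and array, without the correlation between probes or the replicate structure of the real arrays. Other splits of the real acute and saline arrays gave 486 to 1751 probes, so the simulated range does not bound what chance gives. The recovered shares rest on the same setting.

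Alternatives covered unsubtracted signals, other filters and floors, 1 probe per gene, fits of the 2 compared groups alone, the replicate number as a block, array weights, a robust variance trend, other thresholds and leaving out each array. Figures were drawn with matplotlib 3.10.9.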

Results

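The data are 12 expression arrays of the mouse nucleus accumbens, a ventral striatal region of the reward circuit, taken 1 h after the last of 15 daily injections. Saline mice had 15 saline injections. Acute mice had 14 of saline and then 1 of cocaine at 20 mg/kg. Repeated mice had 7 of saline and then 8 of cocaine. Withdrawal mice had 7 of cocaine, 7 of saline and 1 cocaine challenge. Each group had 3 arrays, each a pool from 4 mice aged 8 to 10 weeks, or 12 mice per group. Between 22189 and 23803 of 45281 probes were detected per array, and the median background-subtracted intensity lay between 15.6 and 15.7 on every array after the authors' quantile normalization. The series title names G9a (Ehmt2), a histone H3 lysine 9 methyltransferase, and its repression by repeated cocaine, and the groups ask how the response to a cocaine injection depends on earlier exposure.

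Transcripts of G9a did not pass the adjusted test between any groups. The brightest Ehmt2 probe had a mean log2 intensity of 10.24 ± 0.06 (SD, n = 3) in saline, 10.22 ± 0.14 in acute, 10.18 ± 0.05 in repeated and 10.26 ± 0.12 in withdrawal. Repeated minus saline was −0.06 ± 0.10 (SE), with a 95% interval from −0.28 to 0.17. A second bright Ehmt2 probe gave 0.03 ± 0.09 for the same difference. A dim Ehmt2 probe, detected on 3 withdrawal, 1 repeated and 0 acute arrays, was at least 1.19-fold higher in withdrawal than in acute (limma adjusted p = 0.848, unadjusted interval 0.17 to 1.25 for the fitted log2 difference). Its partner Ehmt1 was dimmer and more variable, at −0.09, −0.31 and −0.52 (SE 0.38) in acute, repeated and withdrawal against saline. None of these passed limma's adjusted test, and the signs of Ehmt2 and Ehmt1 in several comparisons turned when 1 array was left out. The 29 measured enzymes of H3K9 and other H3 lysine methylation did not pass camera as a list in any of the 6 comparisons (median log2 changes 0.02 to 0.07, lowest camera adjusted p = 0.159).

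Acute cocaine against saline asks what a first injection does within 1 h. Immediate early transcription factors, the first genes that active neurons switch on, rose as a group, with a median log2 change of 0.54 and 14 of 17 measured members higher. Egr2, a zinc finger factor, was 2.98-fold higher (1.57 ± 0.22, SE, n = 3), Egr4 was 0.69 ± 0.17 higher, Junb, a partner of Fos, 0.67 ± 0.18 higher, and Crem, a modulator of cAMP-driven transcription, 0.54 ± 0.09 higher. Fos (0.90), Npas4 (0.83), Fosl2 (0.72) and Egr1 (0.40) were higher too, and are named because they passed, a choice made after their values were seen. These 8 passed limma's test with Benjamini-Hochberg adjustment over the list alone (0.000465 for Egr2, 0.0395 for Fos), while 0 passed over all probes. Other probes were weaker, at 0.08 for the second Junb probe and 0.04 to 0.39 for the 3 further Crem probes. Activity-induced effectors rose with a median of 0.19 and 25 of 32 members higher. Among them Arc, which acts at synapses, was 0.83 ± 0.23 higher, Dusp14, a phosphatase, 0.38 ± 0.10 higher, and Tiparp at least 1.57-fold higher, with 0 members past the threshold over the list alone. Camera gave adjusted p = 2.37e-12 and 3.64e-06 for the 2 lists, and adjusted p = 0.0634 for each with an estimated correlation.

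Transcripts of the protein synthesis and energy machinery fell in the same comparison. Ribosomal protein transcripts had a median change of −0.09 with 51 of 56 lower (camera adjusted p = 3.45e-07, and adjusted p = 0.499 with an estimated correlation). Rplp2 (−0.29 ± 0.10) and Rpl36a (−0.24 ± 0.09) had the smallest p. Oxidative phosphorylation subunits had a median of −0.09 with 63 of 72 lower (camera adjusted p = 6.28e-06, and adjusted p = 0.613 with an estimated correlation), Ndufb3 being at −0.22 ± 0.10. Their median was −0.05 without saline replicate 2 and −0.06 without acute replicate 2. In both lists 0 members passed over all probes or over the list alone. Microglia markers lay at −0.11 and blood cell markers at −0.15, and neither passed (camera adjusted p = 0.193 for each).

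Of single genes, Rln3, which encodes the neuropeptide relaxin 3, was at least 1.56-fold higher, Rnd3 was 0.59 ± 0.10 and Spty2d1 1.04 ± 0.17 higher, and the odorant receptor Olfr707 at least 1.31-fold higher after acute cocaine. Acad10, an acyl-CoA dehydrogenase family member, was at −0.97 ± 0.13, although a second Acad10 probe gave 0.16, and Dnajb3 at −0.79, Nlrp10, Chit1, Smagp and Med13l were also lower. None passed the adjusted test. With limma and Benjamini-Hochberg adjustment 0 of 25478 probes passed (lowest adjusted p = 0.174), and 1132 had an unadjusted p under 0.05 where 1274 would by chance. The 1132 became 1595 with the replicate number as a block and 1435 with number 1 blocked against 2 and 3. The series criteria took in 705 probes, 366 higher and 339 lower, of which 77.7% were dim (log2 under 6) against 39.3% of all kept probes. The count became 1131 without acute replicate 3 and 1108 without saline replicate 3. The share of higher probes, 51.9%, fell under 50% with detection on all arrays (49.9%), 1 probe per gene (49.1%) and without acute replicate 3 (44.1%) or saline replicate 1 (46.9%) or 2 (48.9%), and it was 70.0% of 30 probes for unsubtracted signals with an offset, so it favours no direction.

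**Figure D1:**
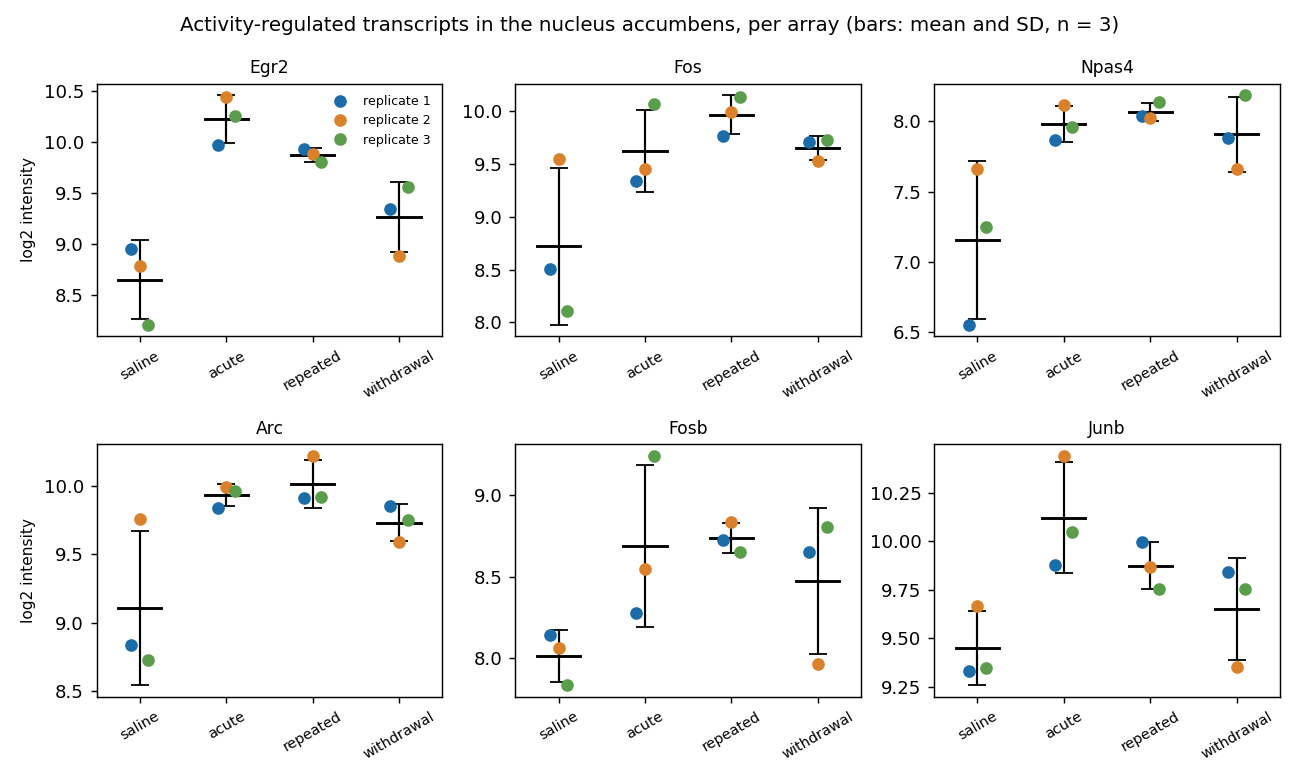
Log2 intensity of Egr2, Fos, Npas4, Arc, Fosb and Junb on each of the 12 arrays by group, with points coloured by replicate number and bars for mean and SD (n = 3). Egr2 averages 8.65 in saline, 10.22 in acute, 9.87 in repeated and 9.26 in withdrawal arrays.

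Repeated cocaine against saline asks what the last of 8 daily injections leaves after 1 h. Immediate early transcription factors rose with a median of 0.34, and 15 of 17 were higher. Fos was 1.24 ± 0.32 (SE, n = 3) higher, Egr2 1.23 ± 0.22, Npas4, a neuronal activity factor, 0.92 ± 0.24, and Crem 0.34 ± 0.09, although a dimmer Crem probe gave −0.50 ± 0.20. With Egr4, Fosl2, Egr1 and Fosb, named after their values were seen, 8 passed limma's test adjusted over the list alone (0.00368 for Egr2, 0.0168 for Fos) and 0 over all probes. Activity-induced effectors rose with a median of 0.14, 24 of 32 being higher. Arc was 0.91 ± 0.23 higher, Dusp1, a MAP kinase phosphatase, 0.47 ± 0.14, Spry4, an inhibitor of growth factor signalling, 0.52 ± 0.16, and Tiparp at least 1.42-fold, with 0 past the threshold over the list alone. Camera gave adjusted p = 3.11e-06 and 0.000564, and adjusted p = 0.220 for each list with an estimated correlation.

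Heat shock genes and chaperones, which refold damaged proteins, also rose in repeated mice, with a median of 0.14 and 15 of 23 higher. Hspa1a, encoding an inducible HSP70, was 4.26-fold higher (2.09 ± 0.36), its co-chaperone Dnajb1 0.53 ± 0.10 higher, Hspa4l 0.77 ± 0.16 and Hsph1 0.42 ± 0.10 higher. With Hspa1b (0.86 ± 0.24), named after its value was seen, 5 passed over the list alone and 0 over all probes. A second Hspa1a probe gave 0.70 ± 0.32 and a second Hspa4l probe 0.36 ± 0.15. The list's camera adjusted p was 0.000526, with adjusted p = 0.220 with an estimated correlation, and it rose to 0.0469 without saline replicate 3. Without repeated replicate 3 the median was 0.22. Of the circadian clock genes, Per2 was 0.56 ± 0.13 higher (second probe 0.55 ± 0.10) and passed over the list alone (0.0260), while the list did not (camera adjusted p = 0.159).

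**Figure D2:**
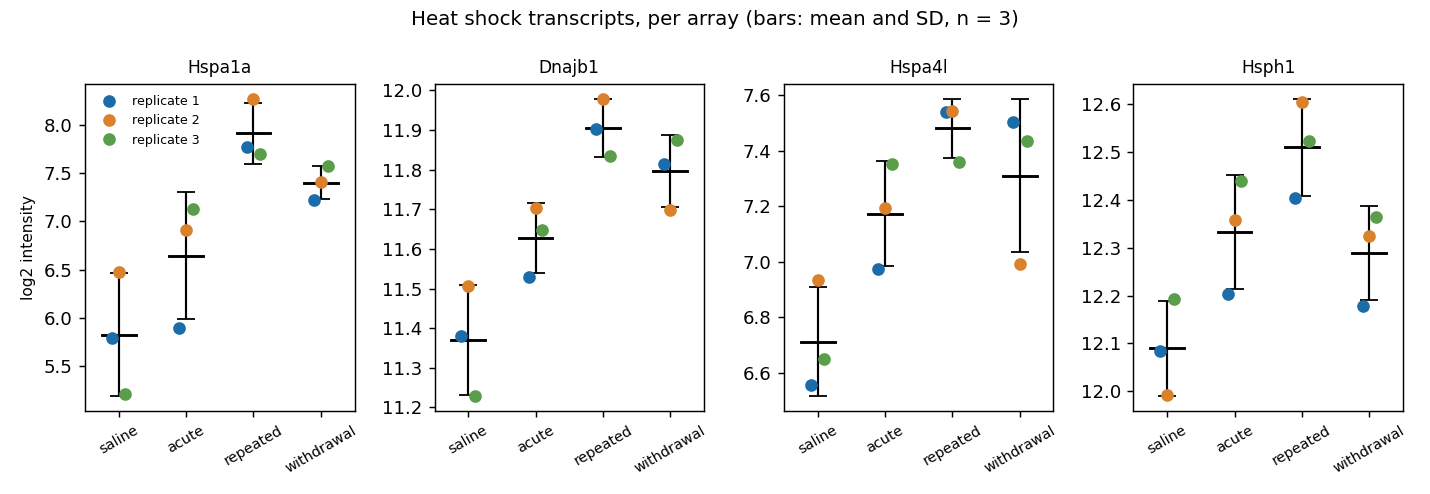
Log2 intensity of Hspa1a, Dnajb1, Hspa4l and Hsph1 on each array by group, coloured by replicate number, with mean and SD (n = 3). Hspa1a averages 5.83 in saline and 7.92 in repeated arrays, with every repeated array above every saline array for these 4 genes.

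Ribosomal protein transcripts fell after repeated cocaine with a median of −0.15, and 51 of 56 were lower. Rpl24 was at −0.34 ± 0.10, Rps13 at −0.36 ± 0.10, Rpl7a at −0.33 ± 0.11 and Rpl13a at −0.30 ± 0.10. Oxidative phosphorylation subunits fell with a median of −0.11, with Sdhc at −0.31 ± 0.08 and Ndufa11 at −0.31 ± 0.09. Camera gave adjusted p = 4.71e-10 and 1.28e-07, and adjusted p = 0.220 and 0.422 with an estimated correlation. The oxidative phosphorylation median was −0.19 without saline replicate 3. In both lists 0 members passed over the list alone or over all probes.

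Several smaller lists passed in the same comparison, each with 0 members past the threshold over all probes. Microglia markers fell, with a median of −0.15 (camera adjusted p = 0.0127, and adjusted p = 0.471 with an estimated correlation), Trem2 being at −0.33 ± 0.10 and Tmem119 at −0.35 ± 0.12. Blood cell markers fell, with a median of −0.34 (camera adjusted p = 0.0224, and adjusted p = 0.422 with an estimated correlation). Of these the leukocyte antigen gene Cd52 (−0.55 ± 0.12) passed over the list alone and the haemoglobin gene Hba-a1 was at −0.47 ± 0.20. Glucocorticoid-responsive genes rose with a median of 0.10 (camera adjusted p = 0.0344, and adjusted p = 0.422 with an estimated correlation). Its leading members went both ways, with the lipid droplet gene Plin4 at 0.82 ± 0.28, Dusp1 as above and Nfkbia, an NF-kappaB inhibitor, at −0.45 ± 0.12. Glutamate receptor and scaffold genes rose with a median of 0.10 (camera adjusted p = 0.0365, and adjusted p = 0.263 with an estimated correlation), with Gria2, an AMPA receptor subunit, at 0.26 ± 0.10. Each of these 4 calls ended when 1 array was left out. Without saline replicate 1 the adjusted p became 0.0787 for microglia (median −0.10), 0.219 for blood (median −0.19) and 0.138 for glutamate receptors, and without saline replicate 3 it became 0.264 for the glucocorticoid list and 0.104 for glutamate receptors. Without repeated replicate 1 it was 0.0731 for blood and for glutamate receptors, without repeated replicate 2 it was 0.230, 0.0699 and 0.0571 for the glucocorticoid, glutamate receptor and microglia lists, and without repeated replicate 3 it was 0.110 for microglia. The glutamate receptor call also ended without acute replicate 2 (0.0510) or 3 (0.0568).

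The single genes with the smallest p in repeated against saline included, besides Hspa1a, Egr2 and Dnajb1, the cold-inducible RNA-binding protein gene Rbm3 (1.23 ± 0.24, second probe 0.99 ± 0.32), Parp3 (at least 1.52-fold higher) and Art5 (at least 1.44-fold higher). Dnajb3, a DnaJ family gene, was at −1.22 ± 0.14 (second probe −0.56 ± 0.50), Olfr352 at least 1.58-fold lower and the ubiquitin-conjugating enzyme gene Ube2l6 at least 1.31-fold lower, and Gm5111, Xrra1 and Dcxr were lower by −0.85, −0.72 and −0.63. None passed the adjusted test. With limma and Benjamini-Hochberg adjustment 0 probes passed (lowest adjusted p = 0.104) and 2264 had an unadjusted p under 0.05, where 1274 would by chance. An excess over that number does not exclude chance, since probes are not independent. The series criteria took in 1169 probes, 634 higher and 535 lower, of which 58.9% were dim. The share of higher probes, 54.2%, was 44.8% with 1 probe per gene, 49.0% without the arrays numbered 1 and 49.9% without repeated replicate 3, and it was 64.6% of 130 probes for unsubtracted signals and 66.0% of 94 for these with an offset. Without a fold minimum 1097 of 2264 were higher.

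**Figure D3:**
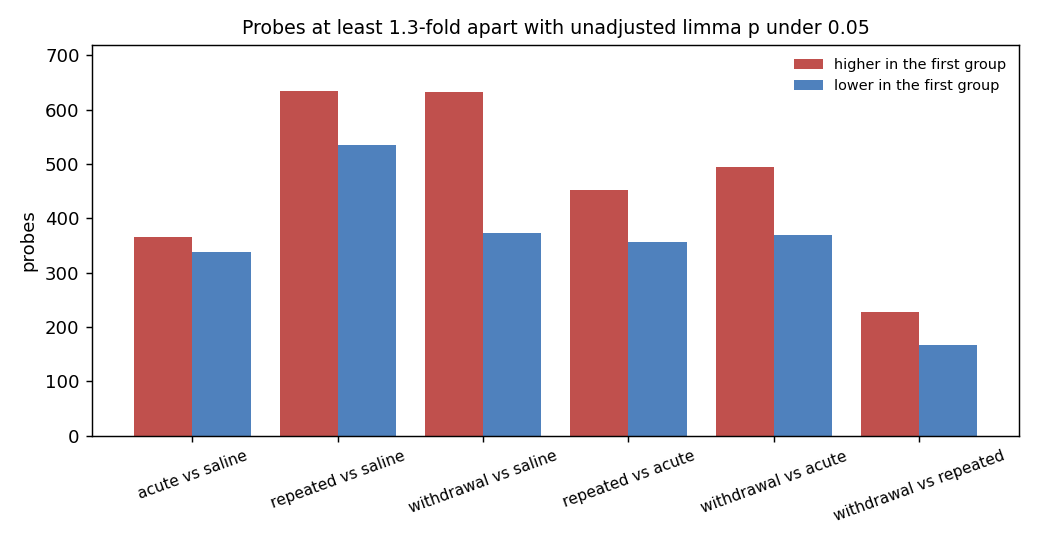
Number of probes at least 1.3-fold apart with an unadjusted limma p under 0.05 in each of the 6 comparisons, in bars for probes higher and lower in the first group. Repeated against saline has 634 and 535, acute against saline 366 and 339.

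Withdrawal and challenge against saline asks how mice given cocaine earlier respond to a renewed injection. Immediate early transcription factors rose with a median of 0.27, 12 of 17 being higher, and effectors with a median of 0.13, 24 of 32 being higher. Fos was at 0.93 ± 0.32 (SE, n = 3), Npas4 at 0.75 ± 0.24, Egr2 at 0.61 ± 0.22, Crem at 0.33 ± 0.09, Arc at 0.62 ± 0.23 and Spry4 at 0.54 ± 0.16, with 0 members past limma's test over the list alone or over all probes. Camera gave adjusted p = 0.00274 and 0.00285, and adjusted p = 0.413 and 0.379 with an estimated correlation. Both list calls ended without saline replicate 3, at 0.113 for each, with an effector median of 0.08. Of the heat shock genes, Hspa1a (1.58 ± 0.36, second probe 0.29), Dnajb1 (0.42 ± 0.10) and Hspa4l (0.60 ± 0.16, second probe 0.11) passed over the list alone, while the list as a whole (median 0.06) had a camera adjusted p of 0.0902. With 1 array left out the list median ran from 0.03 to 0.067. Its camera adjusted p ran from 0.0167, which passes, to 0.734 (without saline replicate 3).

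Ribosomal protein transcripts fell with a median of −0.15, and 50 of 56 were lower. Oxidative phosphorylation subunits fell with a median of −0.14, and 64 of 72 were lower. Without withdrawal replicate 1 the latter median was −0.09. Rpl19 was at −0.28 ± 0.09, Sdhc at −0.29 ± 0.08 and Ndufb7 at −0.39 ± 0.11. Camera gave adjusted p = 2.57e-08 for both, and adjusted p = 0.379 and 0.447 with an estimated correlation. Microglia markers fell with a median of −0.15, 13 of 14 being lower and Tyrobp at −0.40 ± 0.14 (camera adjusted p = 0.00141, and adjusted p = 0.413 with an estimated correlation). Spine actin regulators rose with a median of 0.06, 26 of 30 being higher, among them Kalrn, an exchange factor of dendritic spines, at 0.23 ± 0.10 (camera adjusted p = 0.0411, and adjusted p = 0.379 with an estimated correlation). That call ended without saline replicate 1 (0.180) or 3 (0.0605), withdrawal replicate 1 (0.0967) or 3 (0.0651) and repeated replicate 3 (0.0520). In these lists 0 members passed over the list alone or over all probes. Shared markers of medium spiny neurons, the main striatal cell type, had a median of 0.11 and a camera adjusted p of 0.0561, which became 0.0343 with the replicate number as a block, and adjusted p = 0.606 with an estimated correlation and 0.459 with fry.

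The genes with the smallest p were higher for Zkscan8 (at least 1.18-fold), Dvl2 (at least 1.19-fold), Zfp52 (0.74), the histone gene H3c1 (1.07 ± 0.22), Rbm3 (1.16 ± 0.24, second probe 1.15 ± 0.32) and Rfx7 (0.65), and lower for Dnajb3 (−1.18 ± 0.14, second probe −0.19), Rec114 (−1.28 ± 0.24), Gngt2 (−0.74), Nlrp10 (at least 1.22-fold lower), Lamtor2, of the lysosomal Ragulator complex (−0.46 ± 0.09), and Rnf25 (−0.39). None passed the adjusted test. With limma and Benjamini-Hochberg adjustment 0 probes passed (lowest adjusted p = 0.142) and 1990 had an unadjusted p under 0.05, where 1274 would by chance. The series criteria took in 1005 probes, 632 higher and 373 lower, of which 64.3% were dim, and 1535 probes without saline replicate 3. The share of higher probes, 62.9%, lay between 53.0% (without withdrawal replicate 3) and 69.8% (of 86 probes, unsubtracted signals) over the other fits and omissions.

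**Figure D4:**
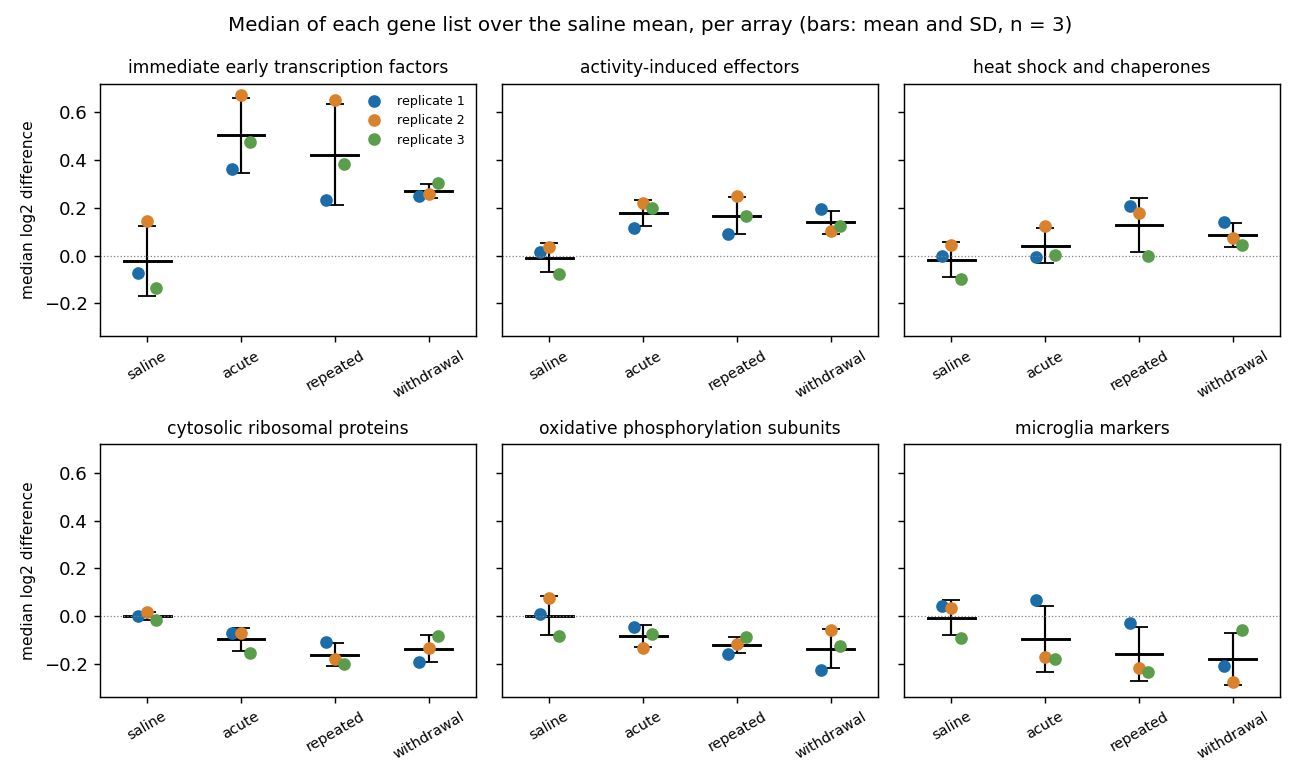
Median log2 difference from the saline mean of 6 gene lists on each array, by group and coloured by replicate number, with mean and SD (n = 3). Ribosomal protein transcripts lie between −0.20 and −0.07 on the arrays with cocaine and between −0.02 and 0.02 on saline arrays. The saline arrays lie around their own mean by construction, since that mean is the reference.

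Repeated against acute cocaine asks how the response changes over 8 daily injections. Heat shock genes were higher in repeated mice, with a median of 0.13 and 17 of 23 higher (camera adjusted p = 0.0223, and adjusted p = 0.838 with an estimated correlation). Hspa1a was at 1.27 ± 0.36 (SE, n = 3), Hsp90b1 at 0.31 ± 0.11, Dnajb1 at 0.28 ± 0.10 and Hspa5, a chaperone of the endoplasmic reticulum, at 0.78 ± 0.29, with 0 past limma's test over the list alone or over all probes. The call ended without acute replicate 3 (0.286) and without repeated replicate 1 (0.163) or 2 (0.115). Immediate early transcription factors had a median of −0.12 and effectors of −0.01, and neither passed (camera adjusted p = 0.298 and 0.869). With 1 array left out the immediate early median ran from −0.215 to −0.023. Its camera adjusted p ran from 0.0450, which passes, to 0.757 (without repeated replicate 1).

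Olfr352, an odorant receptor gene, was the 1 probe past the adjusted test in any of the 6 comparisons. It was at least 2.02-fold lower in repeated than in acute arrays (limma adjusted p = 0.0229), but dim, and detected on 0 of 3 repeated arrays. The fitted difference of −1.39 ± 0.13 therefore depends on the floor, and was −0.06 with a floor of 30. The bound of 2.02-fold carries no sampling error and holds for the background-subtracted values alone. With the replicate number as a block its adjusted p was 0.0714, and it also lost the call without any 1 of 8 arrays of the 12 in turn and without background subtraction (−0.32). Rln3, Xrra1, Gm5111 and Myo1c were lower by −1.09, −0.88, −0.97 and −0.97, and Lipe, the hormone-sensitive lipase gene, was at least 1.47-fold lower. Acad10, Mis12, Zfp607a and Rfx7 were higher by 0.89, 0.70, 0.74 and 0.59, Parp3 at least 1.56-fold and Lrp5 at least 1.48-fold, and none of these others passed. Unadjusted p under 0.05 was reached by 1379 probes, where 1274 would by chance. The series criteria were met by 809, 453 higher and 356 lower, which became 1726 without acute replicate 3, with 4 past the adjusted test. The share of higher probes, 56.0%, was 48.0% without acute replicate 1 and between 50.2% and 62.0% (of 50 probes, unsubtracted signals with an offset) in the other fits and omissions.

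Withdrawal against acute cocaine asks whether earlier exposure changes the response to a single injection. Immediate early transcription factors were lower in withdrawal mice, with a median of −0.21 and 15 of 17 lower (camera adjusted p = 0.00164, and adjusted p = 0.951 with an estimated correlation). Egr2 was at −0.96 ± 0.22 (SE, n = 3) and passed limma's test over the list alone (0.0225), Junb was at −0.47 ± 0.18 and Egr4 at −0.40 ± 0.17, and 0 passed over all probes. The list call ended without acute replicate 3, at 0.0590, and the median was −0.11 without acute replicate 2. Kdm6b, an H3K27 demethylase, was at −0.52 ± 0.11 and passed over the list of H3 lysine methylation enzymes alone (0.0295).

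Zkscan8 (at least 1.21-fold), Dvl2 (at least 1.22-fold), Lrp5 (at least 1.52-fold), Acad10 (0.70), Ttf1 (0.96) and Rfx7 (0.64) were higher and Olfr352 (−0.77), Cyp11b2 (−1.13), Pou5f1 (at least 1.71-fold) and Olfr318 (at least 1.48-fold) lower, none past the adjusted test. With limma and Benjamini-Hochberg adjustment 0 probes passed (lowest adjusted p = 0.452) and 1440 had an unadjusted p under 0.05, where 1274 would by chance. The series criteria were met by 864, 495 higher and 369 lower. That count became 1834 without acute replicate 3. The share of higher probes, 57.3%, was 47.6% of 84 probes for unsubtracted signals and 48.3% of 58 for these with an offset, 50.8% without acute replicate 1 and at most 62.1% (normexp background).

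Withdrawal against repeated cocaine compares a challenge after a week of saline with uninterrupted injections. Immediate early transcription factors were lower in withdrawal mice, with a median of −0.16 and Egr2 at −0.61 ± 0.22 (SE, n = 3; camera adjusted p = 0.0138, and adjusted p = 0.539 with an estimated correlation). Heat shock genes were lower with a median of −0.07 and Hsph1 at −0.22 ± 0.10, and glucocorticoid-responsive genes were lower with a median of −0.04 and Plin4 at −0.94 ± 0.28 (camera adjusted p = 0.0138 and 0.0240, and adjusted p = 0.539 for each with an estimated correlation). Dopamine, opioid and cannabinoid genes were higher with a median of 0.10, 18 of 21 being higher (camera adjusted p = 0.0138, and adjusted p = 0.324 with an estimated correlation). The kappa opioid receptor gene Oprk1 was at 0.43 ± 0.21 and the cannabinoid receptor gene Cnr1 at 0.41 ± 0.22. Blood cell markers were higher with a median of 0.24 (camera adjusted p = 0.0307, and adjusted p = 0.539 with an estimated correlation). In these lists 0 members passed over the list alone or over all probes.

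All 5 calls ended when single arrays were left out. Without repeated replicate 2 the adjusted p was 0.325 for immediate early, 0.272 for glucocorticoid, 0.115 for heat shock and 0.112 for blood genes, and without withdrawal replicate 2 it was 0.0852, 0.702 and 0.192 for the first 3. Without repeated replicate 1 it was 0.228 for heat shock, 0.0789 for dopamine and opioid and 0.228 for blood genes. Without withdrawal replicate 1 it was 0.0731 for dopamine and opioid genes and 0.931 for blood genes, whose median became −0.02. Without withdrawal replicate 3 it was 0.0536 for glucocorticoid and for dopamine and opioid genes and 0.0503 for heat shock genes, and without acute replicate 2 it was 0.0554 for blood genes. Single omissions moved the medians too. For immediate early genes it was −0.27 without repeated replicate 1 and −0.09 without repeated replicate 2. For heat shock genes it was −0.03 and −0.12 without repeated replicate 2 and 3, and −0.12 and −0.04 without withdrawal replicate 1 and 2. For glucocorticoid genes it was −0.09 without repeated replicate 1, and −0.11 and −0.03 without withdrawal replicate 1 and 2. For dopamine and opioid genes it was 0.17 without withdrawal replicate 2, and for blood genes 0.14 without repeated replicate 2 and 0.38 without withdrawal replicate 3.

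The genes with the smallest p here were Zkscan8 (at least 1.25-fold), Dvl2 (at least 1.26-fold), Creg2 (0.42), Olfr352 (at least 1.19-fold), 8430429K09Rik (0.56) and Lipe (at least 1.39-fold), which were higher, and Parp3 (−0.98), Inpp1 (at least 1.19-fold), Art5 (−0.87), Mrpl39 (−0.62), Klhl26 (−0.51) and Col18a1 (−0.42), which were lower. With limma and Benjamini-Hochberg adjustment 0 probes passed (lowest adjusted p = 0.0627), 537 had an unadjusted p under 0.05, fewer than the 1274 that chance would give, and 395 met the series criteria, 227 higher and 168 lower. The 537 became 891 with the replicate number as a block and 1394 with array weights. The share of higher probes, 57.5%, was 42.9% of 14 probes for unsubtracted signals, 46.2% of 13 for these with an offset and 48.5% without withdrawal replicate 3. In the other fits and omissions it was at most 61.1% (without repeated replicate 3), and at an unadjusted p under 0.01, 65 of 102 probes were higher. Over all 4 groups the moderated F test passed 0 probes (lowest adjusted p = 0.149) and gave 1568 with an unadjusted p under 0.05, where 1274 would by chance.

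The 3 comparisons with saline share its arrays, so their overlap lies above 0 without any effect. Repeated and withdrawal shared 268 probes higher and 134 lower under the series criteria, against 15.7 and 7.83 for independent lists and means of 115 and 144.6 in 100 simulations of unchanged groups sharing the saline arrays. Their log2 changes across probes had a correlation of 0.685 (simulated mean 0.49, range −0.144 to 0.896) and a covariance of 0.0483 against 0.0427. Acute and repeated shared 127 and 105 (independent 9.11 and 7.12, simulated 101.5 and 130.1), with a correlation of 0.513 (simulated mean 0.458) and a covariance of 0.0342 against 0.0392. Acute and withdrawal shared 122 and 79 (independent 9.08 and 4.96, simulated 106.9 and 129.4), with a correlation of 0.475 (simulated mean 0.48) and a covariance of 0.0311 against 0.0408. The highest simulated overlaps were 850 and 1338 for repeated with withdrawal, 724 and 1263 for acute with repeated and 733 and 893 for acute with withdrawal. These simulations exchanged residuals over all 12 arrays and so mixed the replicate numbers. With exchanges within numbers, added after the first simulations were seen, the means were 51.8 and 51.0 for repeated with withdrawal, 45.2 and 46.8 for acute with repeated and 50.04 and 52.24 for acute with withdrawal. Overlaps as large came in 2 and 7, 7 and 13, and 9 and 28 of 100 draws. Residuals sum to 0 within a group, so draws that keep a group's arrays together understate these means. The 268 shared higher probes were thus rarely reached within numbers, but this is 1 of several measures and was picked out afterwards. For the same pair of comparisons the correlation was reached in 26 and the covariance in 12 of those 100 draws. Probes are not independent replicates, and whether any overlap exceeds the effect of shared controls was not settled.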

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

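The tests of the 3 patterns weighed below were written after the patterns had been seen but before the value each test measures, whereas the omission of the arrays numbered 1, their use as a block against the others, the normexp background, the floor of 30 and the margins that leave 2 of the tests undecided were chosen after the result was seen.

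In 8 results a cocaine group differed from another cocaine group, both having been set against the same saline arrays, by a direct test of that difference. Adjustment was made within each comparison and not over all 6. Simulations of acute against saline with no changed probe passed a mean of 0.1 probes, so a single probe over 6 comparisons says little. Olfr352 was at least 2.02-fold lower in repeated than in acute arrays (fitted difference −1.39), detected on 0 of 3 repeated and 3 of 3 acute arrays (limma adjusted p = 0.0229, and 0.00851 to 0.876 over the alternatives). Heat shock genes had a median of 0.13 in repeated against acute arrays, 17 of 23 being higher (camera adjusted p = 0.0223, and 0.000313 to 0.838 over camera's alternatives, as in the ranges that follow). In withdrawal against acute arrays the immediate early transcription factors had a median of −0.21, 15 of 17 being lower (camera adjusted p = 0.00164, and 5.15e-05 to 0.951). Against repeated arrays they had a median of −0.16, again with 15 of 17 lower (camera adjusted p = 0.0138, and 0.00175 to 0.539). In the same comparison the median was −0.042 for glucocorticoid-responsive genes, 15 of 23 being lower (camera adjusted p = 0.0240, and 0.000428 to 0.702), and −0.068 for heat shock genes, 16 of 23 being lower (camera adjusted p = 0.0138, and 0.000217 to 0.539). It was 0.10 for dopamine, opioid and cannabinoid genes, 18 of 21 being higher (camera adjusted p = 0.0138, and 0.00185 to 0.324), and 0.24 for blood cell markers, 7 of 8 being higher (camera adjusted p = 0.0307, and 0.000625 to 0.931). Without 1 array the medians of the last 6 moved most, in proportion, to −0.11 (acute replicate 2), −0.09 (repeated replicate 2), −0.11 (withdrawal replicate 1), −0.03 (repeated replicate 2), 0.17 (withdrawal replicate 2) and −0.02 (withdrawal replicate 1). With an estimated correlation and with fry, 0 lists passed in these 3 comparisons.

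Ribosomal protein transcripts were lower after repeated cocaine than after saline, by a median of −0.15 with 51 of 56 lower (camera adjusted p = 4.71e-10, and adjusted p = 0.220 with an estimated correlation). The tables argue against a shift of all bright probes, since the median lay at percentile 0 of 10000 random lists matched on signal, and against a single outlying saline array, since it was at most −0.131 without each in turn (highest adjusted p = 1.02e-07). Each group holds 1 array of each replicate number. A batch shift shared alike by the arrays of a number therefore cancels from the difference and cannot produce it. The block (camera adjusted p = 1.03e-08) leaves the median unmoved by design and adds no test. What stays open is a process that moves the members together from pool to pool, for with an estimated correlation the adjusted p was 0.220 (4.57e-11 to 0.220 over the alternatives). For dissection, marker lists of cortex, neighbouring regions, choroid plexus and ependyma did not pass camera in this comparison, while those of microglia and blood did. Lists that do not pass cannot exclude a difference in dissection. RNA quality or a batch coinciding with the groups were not tested, and none of these can be told apart from cocaine.

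Heat shock transcripts were higher after repeated cocaine than after saline, by a median of 0.14 with 15 of 23 higher (camera adjusted p = 0.000526, and adjusted p = 0.220 with an estimated correlation). The tables argue against a shift of all bright probes, the median lying at percentile 100 of the random lists. A batch shift shared alike by the arrays of a replicate number cancels from this difference too and cannot produce it. The block (camera adjusted p = 0.00147) leaves the median unmoved by design and adds no test. A single outlying array stays open: without each in turn the median stayed between 0.103 and 0.22 (the latter without repeated replicate 3) and the call held, but without saline replicate 3 the camera adjusted p rose to 0.0469, too near the threshold to decide, and over camera's alternatives it ran from 5.68e-06 to 0.220. Warmth, handling and stress of the cocaine mice were not tested and cannot be told apart from the drug, and neither can a batch that coincides with the groups.

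More probes met the series criteria in repeated than in acute arrays against saline, 1169 against 705, an excess of 464. The tables argue against a single outlying saline array as the whole source, since the excess stayed between 347 and 563 without each in turn, with an SD of 166 over all single omissions from the 3 groups. A single noisy acute array stays open: without acute replicate 3 the counts were 1131 and 1227 and the excess was 96, and without acute replicate 1 it was 202. Chance in the assignment of the 6 acute and repeated arrays also stays open, since 20 reassignments are too few to give a share under 0.05, and 2 of them gave an excess as large, the real one included (highest other 494). A stronger response after repeated exposure, the biological reading that the groups offer, may add to the excess, and the values do not tell these apart.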

How the results depend on the processing

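Normexp background, a floor of 30, the block of number 1 against 2 and 3 and the omission of all arrays numbered 1 were tests chosen only after the data were seen, and all other alternatives were planned. Background correction with neqc on non-normalized signals and median scaling in place of quantile normalization were not run, since both tables were already quantile normalized, and a chip block was not run, since no chip is given in the sources used here. Orders below are acute, repeated and withdrawal against saline, then repeated against acute, withdrawal against acute and withdrawal against repeated. Where no cause is given, the cause was not tested.

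Signal over background limits every count under the series criteria, since 77.7%, 58.9%, 64.3%, 71.6%, 73.0% and 84.3% of those probes were dim (log2 under 6) against 39.3% of all kept probes. Unsubtracted signals hold a constant of 60.7 that shrinks the folds of dim probes by construction. With them and a floor of 10 the counts were 50, 130, 86, 84, 84 and 14 in place of 705, 1169, 1005, 809, 864 and 395, and with an offset of 16 they were 30, 94, 63, 50, 58 and 13. Detection on all 12 arrays gave 421 in acute against saline and 536, 552 and 211 in the last 3 comparisons. With 1 probe per gene, which tests fewer probes, they were 275, 482, 365, 320, 338 and 175, and with a floor of 30 they were 302, 677, 545, 373, 383 and 127. Other thresholds change counts by construction. Without a fold minimum they were 1132, 2264, 1990, 1379 and 1440 in the first 5, at 1.5-fold 424, 557, 481, 445, 475 and 223, and at an unadjusted p under 0.01 they were 206, 405, 312, 202, 229 and 102. The replicate block raised the count in every comparison, to 1043, 1575, 1395, 1160, 1352 and 632. In withdrawal against repeated, array weights gave 906, the robust variance trend 238, normexp 204 and the omission of arrays numbered 1 gave 660.

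Probes past limma's adjusted threshold stayed between 0 and 3 in all of these fits. Unsubtracted signals gave 1 in acute against saline (Egr2 at 1.44) and 1 in repeated against saline (Hspa1a at 1.34), with an offset of 16 they gave 1 (Egr2) and 2 (Egr2 and Hspa1a), and under both the F test gave 1. Without a filter on dim probes Pdzrn4 (0.19) alone passed, giving 1 in each comparison of withdrawal and 1 in the F test. With 1 probe per gene Dnajb3 gave 1 in repeated against saline. A floor of 30 gave 1 (Azin2), 3 (Cdip1, Azin2 and Bex2) and 1 (Azin2) against saline, and array weights gave 2 in withdrawal against repeated (Pgls and Zkscan8). These genes are named after their values were seen. Pdzrn4 had the same 0.19 against saline, acute and repeated, and Azin2 the same −0.306 in each cocaine group against saline. Floored values with almost no spread would give such calls from small changes, which was not tested. The 1 call in repeated against acute, Olfr352, became 0 with unsubtracted signals under either offset, without a filter, with detection on all 12 arrays, which drops the probe, in a fit of the 2 groups alone, with the replicate block, the robust variance trend, normexp, a floor of 30 and without arrays numbered 1. Its log2 change was −0.32 unsubtracted, −0.27 with the offset, −0.66 with normexp and −0.06 with a floor of 30, and its adjusted p ran from 0.00851 to 0.876 over the alternatives.

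Lists passing camera numbered 4, 9, 6, 1, 1 and 5, and 0 in all 6 comparisons with an estimated correlation and with fry. Camera's runs differed only in the correlation between genes, preset at 0.01 or estimated, so its loss comes from that setting. The calls therefore rest on the preset. Why fry passed 0 was not tested. Without arrays numbered 1, which leaves 2 arrays per group, 0 lists passed in repeated against acute, where the camera adjusted p of the heat shock list was 0.402 (0.000313 to 0.838 over camera's alternatives). Without them glutamate receptors (0.154) and blood markers (0.371) ceased to pass in repeated against saline, spine regulators (0.224) in withdrawal against saline, and heat shock (0.0663), dopamine and opioid (0.174) and blood genes (0.801) in withdrawal against repeated. Over camera's alternatives these 6 ran from 0.0242 to 0.263, 0.00636 to 0.422, 0.0307 to 0.379, 0.000217 to 0.539, 0.00185 to 0.324 and 0.000625 to 0.931. Apart from the estimated correlation and fry, the immediate early, effector, ribosomal and oxidative phosphorylation lists in acute and in repeated against saline, heat shock in repeated against saline, and microglia, ribosomal and oxidative phosphorylation genes in withdrawal against saline passed in every alternative run. With the estimated correlation included, camera's adjusted p in acute against saline ran from 2.54e-15 to 0.0634 for immediate early, 1.93e-07 to 0.0634 for effector, 7.38e-08 to 0.499 for ribosomal and 2.78e-10 to 0.613 for oxidative phosphorylation genes. In repeated against saline it ran from 3.84e-08 to 0.220 for immediate early, 0.000105 to 0.220 for effector, 3.36e-12 to 0.422 for oxidative phosphorylation, 0.00733 to 0.422 for glucocorticoid-responsive and 0.000213 to 0.471 for microglia genes. In withdrawal against saline it ran from 1.02e-05 to 0.413 for immediate early, 0.000128 to 0.379 for effector, 2.06e-10 to 0.379 for ribosomal, 1.85e-12 to 0.447 for oxidative phosphorylation and 4.95e-05 to 0.413 for microglia genes.

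Some signs near 0 turned. Ehmt1 in acute against saline was at 0.02 with array weights. Without arrays numbered 1, Ehmt2 was at 0.037 in acute against saline, −0.032 in withdrawal against saline and −0.069 in withdrawal against acute, and Ehmt1 was at 0.061 in repeated against acute. In the same fit the effector median was 0.016 in repeated against acute, and blood markers in withdrawal against repeated had a median of 0.061 with camera pointing down.

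With 1 array left out, leaving 2 in its group, probes past the adjusted threshold numbered 0 to 1 in acute against saline (1 without repeated replicate 2, Ccp110), 0 to 1 in repeated and in withdrawal against saline (1 without repeated replicate 3, Dnajb3) and 0 to 1 in withdrawal against acute (1 without saline replicate 2, a probe with no symbol). In repeated against acute they numbered 0 to 4, with 4 without acute replicate 3 (Fut11, Ube2l6, Olfr352 and Tgfbr1) and 0 without saline replicate 3, acute replicate 1 or 2, any repeated replicate and withdrawal replicate 1 or 2. Series criteria counts ran from 682 to 1131 in acute against saline (1131 without acute replicate 3 and 1108 without saline replicate 3) and from 840 to 1535 in withdrawal against saline (1535 without saline replicate 3). They ran from 700 to 1726 in repeated against acute and from 604 to 1834 in withdrawal against acute, the highest being without acute replicate 3 in each. Within 1.5 times of the full count they ran from 1063 to 1455 in repeated against saline and from 352 to 567 in withdrawal against repeated. Lists passing ran from 4 to 7 in acute against saline (7 without saline replicate 2), 6 to 10 in repeated against saline, and 3 to 10 in withdrawal against saline (3 without saline replicate 3, 10 without saline replicate 2). They ran from 0 to 2 in repeated against acute (0 without repeated replicate 2, 2 without acute replicate 1), 0 to 3 in withdrawal against acute (0 without acute replicate 3, 3 without acute replicate 2) and 2 to 5 in withdrawal against repeated (2 without repeated replicate 1). Log2 changes that turned ran from −0.43 to 0.26 for Ehmt1 and −0.081 to 0.055 for Ehmt2 in acute against saline, −0.013 to 0.095 for Ehmt2 in withdrawal against saline, −0.57 to 0.12 for Ehmt1 and −0.112 to 0.024 for Ehmt2 in repeated against acute, −0.03 to 0.11 for Ehmt2 in withdrawal against acute, and −0.04 to 0.054 for the effector median in repeated against acute. Other medians crossed 0 while camera's direction held. Heat shock medians ran from −0.028 to 0.095 in acute against saline and −0.013 to 0.046 in withdrawal against acute. Effector medians ran from −0.061 to 0.021 in withdrawal against acute and −0.119 to 0.012 in withdrawal against repeated, where blood markers ran from −0.019 to 0.377.

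Of 4478 values of single genes under an alternative, 4437 kept their direction and side of the threshold, 9 came to pass it, 17 ceased to and 15 turned. Of 594 values of lists, 486 kept both, 5 came to pass, 99 ceased to and 4 turned. The direction of a list is camera's here, so medians that changed sign while camera's direction held are not among the 4. Most single genes were past no threshold to begin with, so keeping their side says little.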

Other observations

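The comparison of all cocaine arrays with saline, its exact test, the exchanges within replicate numbers and the description of the arrays numbered 1 were chosen only after the result was seen, while the gene lists and the counts of other splits were planned.

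A total of 16 of the 27 lists passed camera in 0 of the 6 comparisons, and so did all 27 with an estimated correlation and with fry. Median log2 changes are given in the order acute, repeated and withdrawal against saline, with camera adjusted p in the same order. Circadian clock genes were at 0.05, 0.08 and 0.05 (0.451, 0.159 and 0.812, with a mean just under 0 in withdrawal), and enzymes of H3 lysine methylation at 0.04, 0.07 and 0.06 (0.299, 0.159 and 0.183). Histone acetylation and DNA methylation enzymes were at −0.03, −0.01 and −0.02 (0.761, 0.899 and 0.961). Among neuronal markers, shared medium spiny genes were at 0.09, 0.03 and 0.11 (0.178, 0.389 and 0.0561), D1 genes at −0.02, 0.02 and −0.04 (0.761, 0.839 and 0.505, with positive means of 0.06 and 0.16 in acute and withdrawal), and D2 genes at −0.04, −0.13 and −0.02 (0.793, 0.255 and 0.961). Interneuron markers were at 0.01, 0.08 and 0.03 (0.872, 0.624 and 0.457, camera pointing down in acute) and cortical markers at 0.08, 0.03 and 0.08 (0.672, 0.999 and 0.927). These group medians do not show equal dissection, since the saline arrays differed among themselves. Against the saline mean, cortical medians were −0.271, 0.423 and −0.133 on saline replicates 1, 2 and 3. Ependymal medians on the same arrays were 0.216, −0.32 and 0.094. Markers of neighbouring septum, hypothalamus and thalamus were at −0.07, −0.01 and −0.16 (0.322, 0.915 and 0.170, with a mean just above 0 in repeated).

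Choroid plexus markers were at −0.11, −0.03 and −0.03 (camera adjusted p = 0.340, 0.845 and 0.961, camera pointing up in withdrawal), and ependymal markers at −0.08, −0.07 and −0.04 (0.322, 0.831 and 0.843, with means of 0.01 and 0.02 in repeated and withdrawal). The choroid plexus transcript Ttr, the transthyretin gene, was at −3.96 ± 1.40 in acute and −1.35 in withdrawal arrays, with SDs of 2.00 and 2.74 among the 3 arrays, and 0.10 in saline. Astrocyte markers were at 0.01, 0.05 and 0.00 (0.859, 0.379 and 0.927, with means of −0.02 and −0.01 in acute and withdrawal). Oligodendrocyte markers were at −0.03, 0.01 and −0.01 (0.799, 0.549 and 0.843, with a mean of −0.07 and camera pointing down in repeated), Opalin being at −0.41 ± 0.11 and Cnp at −0.29 ± 0.10 in repeated arrays. Their precursors were at −0.03, −0.03 and 0.02 (0.872, 0.915 and 0.961, with camera and mean pointing up in repeated and down in withdrawal). Vascular markers were at 0.01, −0.11 and −0.06 (0.761, 0.380 and 0.280), the pericyte gene Pdgfrb being at −0.41 ± 0.13 in acute and −0.44 ± 0.13 in withdrawal arrays. Meningeal markers were at 0.02, 0.07 and 0.07 (0.193, 0.327 and 0.843, with a mean of −0.01 in withdrawal). No single gene named here passed limma's adjusted test.

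Lists that passed elsewhere had these medians where they did not pass. In acute against saline, glucocorticoid-responsive genes were at 0.10 (camera adjusted p = 0.141), heat shock genes at 0.07 (0.193), spine regulators at 0.03 (0.402) and dopamine, opioid and cannabinoid genes at 0.03 (0.433). With 1 array left out the heat shock median there ran from −0.028 to 0.095. Its camera adjusted p ran from 0.0389, which passes, to 0.903 (without saline replicate 3). Glutamate receptors were at 0.05 with a mean of −0.01 (0.563). In repeated against saline, spine regulators were at 0.08 (0.0548) and dopamine, opioid and cannabinoid genes at −0.11 (0.793). In withdrawal against saline, glucocorticoid-responsive genes were at −0.03 with camera pointing up (0.843), glutamate receptors at 0.04 (0.122), dopamine, opioid and cannabinoid genes at 0.11 (0.143) and blood markers at −0.11 (0.467). A further and dim Ehmt2 probe, detected on 5 of 12 arrays, was at −0.35, −0.25 and 0.37 in acute, repeated and withdrawal against saline (SE 0.24), and at 0.71 in withdrawal against acute (95% interval 0.17 to 1.25, at least 1.19-fold) and 0.61 against repeated (0.07 to 1.16), neither interval holding 0. No acute array detected it, so its fitted differences from acute depend on the floor. A second Ehmt1 probe was at −0.10, 0.06 and 0.17 (SE 0.27). None of these passed limma's adjusted test.

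The arrays are ordered by replicate number as well as by treatment. For each of the 12 arrays the closest array of another group, by correlation of deviations from the group means, had its own number. The first principal component held 26.0% of the variance and parted the 4 arrays numbered 1 (scores 28.4 to 37.5) from the other 8 (−34.7 to 2.09). Correlations among arrays numbered 1 ran from 0.386 to 0.468, and same-numbered correlations among the others from 0.0255 to 0.344. The labels name no day, litter or chip that the numbers would stand for.

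Splits of the 6 arrays of a comparison into 3 and 3 number 10, too few to give a share under 0.05. Counts under the series criteria were as large as the real one in 9 of 10 splits for acute against saline (705, highest other 1751) and in 3 for repeated against saline (1169 and 1606). They were as large in 4 for withdrawal against saline (1005 and 1630), in 7 for repeated against acute (809 and 1674), in 6 for withdrawal against acute (864 and 1493) and in 10 for withdrawal against repeated (395 and 1539). A split with several times the real count, as in the last comparison, points to a structure of the samples. Where the numbers pair the arrays, the 4 splits that part all 3 pairs gave at most 499 besides the real 1169 in repeated against saline, 598 besides 1005 in withdrawal against saline and 632 besides 809 in repeated against acute, and the splits that part 1 pair gave the highest counts. For probes past limma's adjusted threshold a real count of 0, which any split reaches, was met in 10 of 10 splits for the 3 comparisons with saline (highest other 13, 1 and 0) and for withdrawal against acute and against repeated (1 and 0). In repeated against acute, 2 of 10 splits gave as many as the real 1 probe (highest other 2).

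Over free draws of the 12 arrays into 4 groups of 3, chance was not excluded for the F test's 1568 probes with an unadjusted p under 0.05, a count reached in 24 of 100 draws (highest other 3641). Its 0 probes past the adjusted threshold are reached by any draw, 100 of 100 (highest other 33), which decides nothing. Free draws also mix the replicate numbers, by which the arrays are structured, and this can raise their counts. Among 100 exchanges of arrays within replicate numbers, 3 gave as many with an unadjusted p under 0.05 (highest other 1811), and 100 gave at least 0 past the adjusted threshold (highest other 3). Chosen after the free draws, these exchanges decide nothing about chance either.

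A hypothesis is that the 3 cocaine groups share a response that each comparison alone is too small to show. In the 9 cocaine arrays against the 3 saline arrays, limma with Benjamini-Hochberg adjustment passed 0 probes (lowest adjusted p = 0.155), 2143 had an unadjusted p under 0.05 (1274 by chance), and 801 met the series criteria, 458 higher and 343 lower. Chance was not excluded for that count, which 30 of 100 free draws reached (highest other 1421), nor under exchanges within replicate numbers, of which 4 of 64 reached it (highest other 1311). The median of the immediate early transcription factors, 0.403 over the fitted changes, was reached by the real grouping alone, 1 of 100 draws (highest other 0.368). That share decides nothing about chance, although it met the bound set for it, because the comparison was chosen after this list had been seen to rise in all 3 comparisons with saline. An exact test of the 27 list scores over all 220 splits, whose smallest possible p is 0.00455, gave a Benjamini-Hochberg adjusted p of 0.041 for 3 lists. Immediate early factors were 0.37 and effectors 0.17 higher, each with 9 of 9 cocaine arrays above every saline array, and ribosomal proteins were at −0.12 with 9 of 9 below. Interneuron markers came next at 0.06 (8 of 9 above, exact adjusted p = 0.0614), and oxidative phosphorylation (−0.13), H3 lysine methylation (0.07) and spine (0.06) genes followed at 0.123. Heat shock (0.11) and microglia (−0.14) genes were at 0.232. Exchanges within replicate numbers number 64, with a smallest possible p of 0.0156, which the first 3 lists and the spine list reached. Adjusted over 27 lists this exact p became 0.105, and the exchanges are too few to decide whether the numbers play a part. The lists and arrays are those on which the pattern was seen, so this is not separate evidence, and with an estimated correlation 0 lists passed in any of the 6 comparisons.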
